A study of Mus musculus with 27 samples.

How the data were processed

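Total RNA from KUSA4b10 cells was measured on 27 Affymetrix expression arrays, each read in 1 biotin-labelled colour, with 3 arrays in each of 9 groups. KUSA4b10 is a mouse line of bone marrow stromal cells that can take on osteoblast features in culture. Per the labels, cells stayed untreated or received a peptide. It was an N-terminal fragment of parathyroid hormone, PTH, at 10 nM, or a longer form of parathyroid hormone-related protein, PTHrP, at 20 nM. RNA was collected after 1, 6 or 24 h. Both ligands act through the same receptor, the product of Pth1r. The labelled doses and peptide lengths differ, so ligand, peptide length and dose are not separable in any comparison of PTHrP with PTH.

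The intensity values deposited by the authors are summarised per probe set and were made with RMA, per the submitters' processing notes. Per the design text of the series, the study was published in 2008 and its values were normalized again for the deposit in 2013, so they can differ from those behind the publication. The software version, the background model and the probe set definitions are not given in the sources used here. The table holds 45101 probe sets on a linear scale, from 6.79 to 36257, with array medians from 83.03 to 90.87. Upper quartiles ran from 283.1 to 332.4, so the distributions were close but not identical between arrays. RMA values are often given as log2, and the test plan allowed for either scale, so log2 was taken first and every difference below is a log2 difference or its fold. RMA subtracts background and quantile-normalizes arrays, which pulls the distributions of all arrays together. A change that moved most transcripts the same way would therefore be hidden, and fold changes of dim genes are understated. No 2 arrays held identical values.

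Control probe sets, 64 in all, were left out of the tests. A probe annotation table paired 34958 probe sets with 1 gene symbol and 932 with several, and did not list 9211, controls included, which are unnamed here. Of the probe sets with 1 symbol, 34754 matched a RefSeq gene table by gene identifier and 0 symbols needed an update. Each of 18193 genes was represented by its probe set with the highest mean over the 27 arrays, and 9010 genes had more than 1. Genes with a log2 value of at least 5 on at least 3 arrays were tested, 15711 in all. No genome coordinates were used.

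Groups were compared with limma 3.58.1 in R 4.3.3. Its lmFit and eBayes functions fitted 9 group means to all 27 arrays, so that every comparison shared 1 estimate of the spread per gene, with 18 residual and 5.54 prior degrees of freedom. Tests were two-sided and adjusted p-values are Benjamini-Hochberg values over the 15711 genes within a comparison, with a threshold of 0.05. Errors given as ± after a log2 fold change are standard errors from that fit, and errors given as SD are over the 3 arrays of a group. The 15 comparisons were each ligand against the untreated cells of the same time, PTHrP against PTH at each time, the change of each ligand's effect from 1 to 6 h and from 6 to 24 h, and untreated cells at 6 and 24 h against 1 h. The number of arrays limits the precision: the median SE was 0.102 for a difference of 2 groups and 0.144 for a change of effect with time. Comparisons of a single value between 2 groups used two-sided exact permutation tests, and with 3 arrays against 3 the smallest p these can give is 0.1. The labels do not say that replicates are separate cultures, so p-values measure only the spread between these samples, which may be technical. The labels number the replicates of each group alike and give no shared culture or day. After group means were removed, same-numbered arrays of 2 groups at the same time correlated over 0.1 in every pair for 1 of 9 pairs of groups, untreated cells and PTHrP at 1 h, and the number of these arrays was used as a block in an alternative chosen after that was seen. No slide or scan date was given, so neither the slide nor the background correction could be varied.

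Gene lists, 28 in all with 570 genes of which 525 were on the array, were written before the data were examined, as were the groups, the tests, the filters and most alternatives. They cover immediate early genes, cAMP and G protein-coupled receptor feedback, osteoclast-regulating factors, gp130 cytokine signalling, ephrins and Eph receptors, osteoblast and osteocyte genes, Wnt, BMP and TGF-beta, IGF and Notch signalling, matrix proteases, extracellular matrix, chemokines, prostaglandins, clock genes, angiogenic factors, cell cycle, cholesterol synthesis, the unfolded protein response, heat shock, glycolysis and hypoxia, the interferon response, ribosomal proteins, and markers of adipocytes, chondrocytes, muscle, macrophages and blood cells, and endothelium. Some genes are on several lists. Each list was tested with camera at its preset inter-gene correlation of 0.01 and again with a correlation estimated per list, adjusted over the 28 lists. The limma function fry, which tests whether the genes of a list move on balance in 1 direction and does not set them against other genes, was an alternative. The study chose Efnb2 on these samples, and the ephrin list was written around it from the title, so neither is independent evidence.

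Genes were named by a rule fixed with the lists. For each ligand against control it took the 10 largest increases and the 10 largest decreases among genes past the threshold whose 3 treated arrays all lay above, or all below, the 3 control arrays, and skipped clone and predicted names. For each list it took up to 4 members past the threshold by size, or up to 2 with the lowest adjusted p where none passed. It took the 5 largest in each direction for PTHrP against PTH and the 3 largest for the changes with time. Efnb2, Ephb4, Pth1r, Tnfsf11, Tnfrsf11b, Sost, Il6 and Nr4a2 were always included. The relative size of the responses to PTHrP and PTH was added after the counts of genes had been seen: over genes that changed more than 2-fold by the mean of both ligands, each array's mean shift from the control mean, signed by the direction of the change, was computed.

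PTH and PTHrP were compared with the same 3 control arrays, so 100 simulated data sets of unchanged groups gave the correlation and covariance that shared controls alone produce. The fit was tested on simulated data in which 40 genes were changed at each of 5 sizes. For PTH against control at 1 h it called 100% of genes raised by 1 log2 unit, 97.5% of those lowered by 1, 72.5% of those raised by 0.5, 62.5% of those lowered by 0.5, and 8 of 15511 unchanged genes. The simulated noise was drawn separately for each gene, with 1 SD per gene on all arrays. In the real data 1 component held 37.5% of the variance left within groups, so these rates may not hold for the real arrays. Alternatives were no filter, a stricter filter of log2 7, the mean of a gene's probe sets, each probe set on its own, arrays shifted to 1 median, cyclic loess between arrays, only the arrays compared, array weights, a trended and robust prior from statmod 1.5.0, the replicate number as a block, a test against a 1.5-fold change, and leaving out each array in turn. Added after the data had been seen were the array upper quartile as a covariate, the fit without 1 array of the PTHrP 1 h group, and further settings for the gene lists, the overlap of the ligands and the relative size of their responses. Tables were prepared with pandas 2.3.3 and plots with matplotlib 3.10.9 in Python 3.11.15.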

Results

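Expression was measured in KUSA4b10 mouse marrow stromal cells on 27 arrays, 3 in each of 9 groups: untreated, PTH at 10 nM and PTHrP at 20 nM, at 1, 6 and 24 h. PTH and PTHrP are related peptides that share a receptor on cells of the osteoblast lineage, and the title of the study asks how they control Efnb2, the gene of ephrin B2. Array medians ran from 83.03 to 90.87 on the linear intensity scale. Within a group, the correlation of log2 values between arrays (across genes, which are not independent replicates) was 0.992 to 0.9978, except with PTHrP at 1 h, where replicate 3 stood apart and the lowest was 0.9831. The first component of all arrays held 43.7% of the variance and parted 24 h from the earlier times, and the next held 25.4% and parted treated from untreated cells at 6 h. The 3' probe set of Actb, beta-actin, exceeded its 5' probe set by 0.23 ± 0.02 log2 units in untreated cells at 1 h and by 0.38 ± 0.01 at 24 h (SD, n = 3). With PTH and PTHrP this ratio, which rises when RNA is degraded, was 0.42 ± 0.01 and 0.44 ± 0.01 at 24 h, each above all 3 control arrays (exact p = 0.1, the smallest possible), so the Actb ratio moved with both time and treatment. It was also above the controls with PTH at 1 h, at 0.27 ± 0.02, and at 6 h, at 0.34 ± 0.01 against 0.26 ± 0.05 (exact p = 0.1 for each). With PTHrP the Actb ratio was 0.276 ± 0.031 at 1 h and 0.303 ± 0.045 at 6 h, and its arrays overlapped the controls (exact p = 0.2 and 0.3). The same ratio of Gapdh, a glycolytic enzyme gene, went the other way with time in untreated cells, from -0.18 ± 0.01 at 1 h to -0.21 ± 0.01 at 24 h (exact p = 0.1). At 24 h the Gapdh ratio with PTH and PTHrP differed from control by -0.003 and -0.011 (exact p = 0.8 and 0.2), and at 6 h it was higher by 0.033 and 0.052 (exact p = 0.1 for each).

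Untreated cells changed with time in culture, which is the background for each treatment. From 1 to 6 h the early transcription factor genes Egr3, Fosb and Egr2 fell by 2.88 ± 0.15, 2.75 ± 0.16 and 2.41 ± 0.15 log2 units (SE, n = 3). Of 29 immediate early genes, which respond to stimuli without new protein synthesis, 14 fell and 1 rose, and 23 fell and 1 rose when adjusted over the list alone (camera adjusted p = 9.27e-41, and adjusted p = 0.00176 with an estimated correlation). By 24 h, 25 of 29 cell cycle genes had fallen below their 1 h level, 26 adjusted over the list alone (adjusted p = 1.84e-31, and adjusted p = 0.00058 with an estimated correlation). At that time Oasl2, an interferon-induced gene, and Gadd45a, a stress-induced inhibitor of growth, had risen by 2.69 ± 0.41 and 2.39 ± 0.18. Of 22 genes of the unfolded protein response, 17 had risen (20 adjusted over the list alone, camera adjusted p = 1.61e-13), and of 16 cholesterol synthesis genes 14 had fallen (15 adjusted over the list alone, camera adjusted p = 6.39e-14). Those calls were lost with adjusted p = 0.218 and adjusted p = 0.0703 with an estimated correlation. Over all genes, 356 differed between 1 and 6 h (113 higher, 243 lower) and 3635 between 1 and 24 h (1821 higher, 1814 lower). The 6 h count was 175 without control 1 h replicate 1, 196 without control 1 h replicate 3, and 220, 200 and 178 without control 6 h replicates 1, 2 and 3.

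After 1 h, PTH strongly raised genes that signal, switch on transcription or damp signalling. Il6, the gene of an inflammatory cytokine, stood at 11.2 ± 0.78 against 5.92 ± 0.66 in untreated cells (log2 intensity, SD, n = 3). Nr4a2, an orphan nuclear receptor, rose by 4.42 ± 0.24 log2 units (SE). Rgs2, a regulator of G protein signalling, rose by 3.80 ± 0.14 and the transcription factor gene Fos by 3.63 ± 0.15. PTHrP raised Nr4a2 by 4.25 ± 0.24, Il6 by 4.29 ± 0.37, Rgs2 by 3.49 ± 0.14 and Fos by 3.37 ± 0.15. Both ligands also raised Dusp1, a MAP kinase phosphatase, Gem, a small GTPase, Foxc2, a forkhead transcription factor, and Sik1, a salt-inducible kinase, by 2.65 to 3.07. PTH raised Ptgs2, the inducible prostaglandin synthase, by 2.63 ± 0.21, and PTHrP raised Vdr, the vitamin D receptor, by 2.40 ± 0.22. Each is given for 1 ligand because of the naming rule, and at 1 h 0 genes passed for PTHrP against PTH. Decreases were smaller: Cdk5r1, an activator of the kinase Cdk5, fell by 1.19 ± 0.11 with PTH and by 1.34 ± 0.11 with PTHrP, and Txnip, a thioredoxin-binding protein, fell by 1.10 ± 0.13 with PTH. In each of these named genes, the 3 treated arrays lay on 1 side of the 3 control arrays, and each passed the threshold over all genes (for Cdk5r1, adjusted p = 8.72e-08 with PTH and 1.35e-08 with PTHrP).

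At 1 h camera called several of the gene lists with both ligands, though many members of each did not pass over all genes. Of 27 genes of cAMP and G protein-coupled receptor feedback, 9 rose with PTH and 10 with PTHrP and 0 fell, while adjusted over the list alone 10 rose and 1 fell, and 11 rose and 1 fell (camera adjusted p = 4.92e-17 and 2.14e-16, and adjusted p = 6.46e-05 and 0.000169 with an estimated correlation). Of 29 immediate early genes, 12 rose and 2 fell with PTH (14 and 8 adjusted over the list alone, adjusted p = 6.3e-19). Btg2, an inhibitor of proliferation, rose by 2.36 ± 0.13. With PTHrP 12 rose and 3 fell (14 and 6 adjusted over the list alone, adjusted p = 1.5e-11). The PTH call passed with an adjusted p = 0.0109 with an estimated correlation, and the PTHrP call missed it at adjusted p = 0.0512 with an estimated correlation. Of 15 factors that regulate osteoclasts, 5 rose with either ligand (5 and 6 adjusted over the list alone, adjusted p = 4.26e-11 and 2.39e-08, and adjusted p = 1.99e-05 and 0.000169 with an estimated correlation). They included Tnfsf11, the gene of RANKL, the main signal for osteoclast formation, which rose by 1.79 ± 0.27 and 1.68 ± 0.27. Lif, a cytokine gene, rose by 2.22 ± 0.11 and 1.96 ± 0.11. Tnfrsf11b, the gene of osteoprotegerin, a decoy receptor for RANKL, did not pass, with differences of 0.08 ± 0.14 and -0.21 ± 0.14. Of 17 genes of gp130 cytokine signalling, 5 rose with either ligand (8 and 7 adjusted over the list alone, adjusted p = 9.46e-14 and 4.59e-07, and adjusted p = 1.99e-05 and 0.00107 with an estimated correlation). Il11 rose by 1.29 ± 0.12 and 1.14 ± 0.12. Of 26 genes of BMP and TGF-beta signalling, 5 rose with either ligand (7 and 8 adjusted over the list alone, adjusted p = 2.73e-11 and 7.76e-07, and adjusted p = 1.99e-05 and 0.00047 with an estimated correlation). The inhibitory Smad genes Smad6 and Smad7 rose, the former by 1.24 ± 0.13 and 1.38 ± 0.13 and the latter by 0.88 ± 0.10 and 0.68 ± 0.10. Of 11 prostaglandin genes, 3 rose with either ligand, also adjusted over the list alone (adjusted p = 0.000149 and 0.000825, and adjusted p = 0.0109 and 0.0259 with an estimated correlation). Ptger4, a prostaglandin receptor gene, rose by 1.97 ± 0.14 and 1.75 ± 0.14.

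In all, 273 genes changed with PTH at 1 h (226 higher, 47 lower) and 285 with PTHrP (246 higher, 39 lower), of which 79 and 66 changed more than 2-fold. Without replicate 3 of the PTHrP group, the array that stood apart, 931 genes passed with PTHrP (612 higher, 319 lower), so 65.7% were higher instead of 86.3%. With only the arrays of the groups compared, 103 passed with PTHrP (98 higher, 5 lower). Array weights gave 928 higher and 836 lower with PTHrP, and 523 higher and 279 lower with PTH. The same omission gave 442 genes with PTH, a comparison that array enters only through the estimate of the spread that all groups share.

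At 6 h the responses were broadest: the RANKL gene Tnfsf11 and several cytokine genes rose, and genes of osteoblasts and osteocytes such as Dmp1 fell. Tnfsf11 stood at 10.45 ± 0.17 with PTH and 9.33 ± 0.12 with PTHrP, against 5.1 ± 0.39 in untreated cells (log2 intensity, SD, n = 3), so it rose by 5.35 ± 0.27 and 4.22 ± 0.27 (SE). Tnfrsf11b fell by 3.10 ± 0.14 and 2.97 ± 0.14. Il6 rose by 6.08 ± 0.37 with PTH and 3.36 ± 0.37 with PTHrP. Other increases were those of the cytokine genes Il33 and Il11 by 4.77 ± 0.16 and 4.63 ± 0.12 with PTH and by 2.97 ± 0.16 and 3.34 ± 0.12 with PTHrP, and Vdr by 4.29 ± 0.22 and 3.59 ± 0.22. Dmp1, a matrix protein gene of osteocytes, fell by 3.37 ± 0.34 and 2.63 ± 0.34, and Smpd3, a neutral sphingomyelinase, differed by -5.16 ± 0.18 and -4.17 ± 0.18. Pdgfa, a growth factor gene, changed by -3.74 ± 0.09 and -2.95 ± 0.09, and Mef2c, a transcription factor gene, by -3.69 ± 0.28 and -2.82 ± 0.28. Pth1r, the gene of the receptor of both ligands, fell by 1.12 ± 0.10 (adjusted p = 1.21e-09) with PTH and by 0.40 ± 0.10 (adjusted p = 0.00337) with PTHrP. Sost, the gene of sclerostin, an inhibitor of bone formation, lay near log2 5 and did not pass with either ligand at any time.

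By group, 15 of 27 feedback genes rose and 4 fell with PTH, and 16 rose and 3 fell with PTHrP (15 and 4, and 17 and 3, adjusted over the list alone, with adjusted p = 3.77e-08 and 1.88e-08, and adjusted p = 0.00962 and 0.00637 with an estimated correlation). Ramp3, a receptor activity-modifying protein, rose by 4.00 ± 0.11 and 2.58 ± 0.11. Pde4b, a phosphodiesterase that degrades cAMP, rose by 3.83 ± 0.17 with PTH. Of 17 gp130 genes, 11 rose and 1 fell with PTH and 9 rose and 1 fell with PTHrP (11 and 1, and 10 and 1, adjusted over the list alone, with adjusted p = 4.42e-09 and 2.81e-08, and adjusted p = 0.000794 and 0.00156 with an estimated correlation). Bcl3, a co-regulator of NF-kappa B, rose by 2.56 ± 0.11 and 2.11 ± 0.11. Socs3, a feedback inhibitor of cytokine signalling, rose by 2.52 ± 0.21 and 2.14 ± 0.21. Of 15 osteoclast-regulating factors, 8 rose and 2 fell with PTH and 5 rose and 2 fell with PTHrP, also adjusted over the list alone (adjusted p = 0.00128 and 0.0154, and adjusted p = 0.019 and 0.0905 with an estimated correlation). Of 20 osteoblast and osteocyte genes, 3 rose and 8 fell with PTH and 2 rose and 8 fell with PTHrP (3 and 9, and 2 and 8, adjusted over the list alone, with adjusted p = 0.0161 and 0.0118, and adjusted p = 0.32 and 0.381 with an estimated correlation). Sp7, the gene of osterix, fell by 1.85 ± 0.11 and 1.20 ± 0.11, while Pdpn, the gene of podoplanin, rose by 1.44 ± 0.10 with PTH. Immediate early genes had split, with 15 of 29 up and 6 down with PTH, also adjusted over the list alone (adjusted p = 0.000829, and adjusted p = 0.415 with an estimated correlation), and 13 up and 6 down with PTHrP (13 and 7 adjusted over the list alone, adjusted p = 0.0773). Fosl1, an AP-1 transcription factor, rose by 3.04 ± 0.14 and 2.41 ± 0.14, and Egr3 fell by 2.64 ± 0.15 and 2.31 ± 0.15.

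Stress and metabolic groups rose at 6 h by camera at its preset correlation. Of 22 genes of the unfolded protein response, which answers misfolded protein in the endoplasmic reticulum, 18 rose with PTH and 17 with PTHrP (19 and 17 adjusted over the list alone, adjusted p = 1.39e-09 and 1.88e-08), but adjusted p = 0.294 and 0.381 with an estimated correlation. Trib3 and Ddit3, both induced by such stress, rose by 1.98 ± 0.35 and 1.75 ± 0.18 with PTH. Of 16 cholesterol synthesis genes, 13 rose with PTH (14 adjusted over the list alone, adjusted p = 5.27e-09, and adjusted p = 0.19 with an estimated correlation). Sqle and Fdft1, both of that pathway, rose by 1.53 ± 0.11 and 1.21 ± 0.11. With PTHrP 6 rose, also adjusted over the list alone (adjusted p = 0.0246, and adjusted p = 0.578 with an estimated correlation), and the call was lost without control 6 h replicate 2 (adjusted p = 0.117) or PTHrP 6 h replicate 2 (adjusted p = 0.214). Of 20 genes of glycolysis and hypoxia, 9 rose with either ligand (10 and 12 adjusted over the list alone, adjusted p = 3.97e-06 and 1.73e-06, and adjusted p = 0.32 and 0.381 with an estimated correlation). Slc2a1, a glucose transporter gene, rose by 1.71 ± 0.21 and 1.22 ± 0.21. Cell cycle genes fell with PTHrP, 16 of 29 and 19 adjusted over the list alone (adjusted p = 3.41e-07, and adjusted p = 0.127 with an estimated correlation). With PTH 10 fell and 3 rose, also adjusted over the list alone, and the list did not pass (adjusted p = 0.109). The DNA replication gene Mcm6 fell by 0.89 ± 0.13 and 0.87 ± 0.13.

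At 6 h, 4605 genes changed with PTH (1789 higher, 2816 lower) and 3288 with PTHrP (1367 higher, 1921 lower), of which 537 and 294 changed more than 2-fold. More PTHrP calls were higher than lower after cyclic loess (1860 and 1762), with array weights (3512 and 3440), with the array upper quartile as a covariate (1831 and 1794) and without PTHrP replicate 2 (1374 and 1334). Against a 1.5-fold change instead of any change, 569 passed with PTH (304 higher, 265 lower) and 286 with PTHrP (154 higher, 132 lower).

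After 24 h Nr4a2 no longer passed with either ligand, and most of the measured osteoblast and osteocyte genes were below untreated cells with PTH. Dmp1 fell by 4.61 ± 0.34 with PTH and 3.96 ± 0.34 with PTHrP (SE, n = 3). Omd, the gene of osteomodulin, fell by 3.08 ± 0.17 and 1.92 ± 0.17, and Postn, the gene of periostin, by 2.70 ± 0.19 and 2.47 ± 0.19. Panx3, a channel protein gene of bone and cartilage, fell by 3.33 ± 0.16 with PTH. Prg4, the gene of lubricin, rose by 2.84 ± 0.18 with PTH and 1.51 ± 0.18 with PTHrP, and Csgalnact1, an enzyme of chondroitin sulphate synthesis, by 2.45 ± 0.12 and 2.30 ± 0.12. Socs3 rose by 2.18 ± 0.21 and 2.30 ± 0.21. The acute phase gene Saa3 and the chemokine gene Cxcl5 were among the 10 largest increases with PTHrP, at 2.24 ± 0.29 and 2.23 ± 0.26. Tnfrsf11b was lower by -1.65 ± 0.14 with PTH and -1.11 ± 0.14 with PTHrP. Tnfsf11 passed with PTH at 0.93 ± 0.27 (adjusted p = 0.0257), but with any of control replicates 1, 2 and 3 or PTH replicates 1 and 3 left out its adjusted p was 0.0546 to 0.124, and with PTHrP its difference was 0.44 ± 0.27 (adjusted p = 0.51). Il6 passed with PTHrP at 1.40 ± 0.37 (adjusted p = 0.0187), but not without control replicate 2, control replicate 3 or PTHrP replicate 2, where its adjusted p was 0.0899 to 0.145. Pth1r fell by 0.82 ± 0.10 with PTH.

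Of 20 osteoblast and osteocyte genes, 14 fell and 0 rose with PTH and 9 fell and 1 rose with PTHrP (15 and 0, and 12 and 1, adjusted over the list alone, with adjusted p = 1.5e-19 and 3.31e-15, and adjusted p = 0.000732 and 0.00338 with an estimated correlation). Ibsp, the gene of bone sialoprotein, differed by -2.85 ± 0.17 log2 units with PTH. On the PTHrP arrays Ibsp lay at 10.56 to 10.93, below 12.06 to 12.51 in untreated cells (log2 intensity). Of 28 extracellular matrix genes, 14 fell and 1 rose with PTH and 8 fell and 1 rose with PTHrP (16 and 1, and 10 and 1, adjusted over the list alone, with adjusted p = 3.89e-11 and 4.35e-06, but adjusted p = 0.0963 and 0.238 with an estimated correlation). Fmod, the gene of fibromodulin, fell by 1.40 ± 0.09 with PTH. Tnc, the gene of tenascin C, fell by 1.04 ± 0.09 with PTHrP. Vcan, the gene of versican, rose by 1.53 ± 0.18 and 1.36 ± 0.18. Of 26 genes of BMP and TGF-beta signalling, 8 fell and 0 rose with PTH and 6 fell and 1 rose with PTHrP (10 fell and 2 rose, and 8 fell and 2 rose, adjusted over the list alone, with adjusted p = 0.000105 and 0.00586, and adjusted p = 0.00725 and 0.0386 with an estimated correlation). Id3, a BMP target, fell by 1.83 ± 0.10 and 0.70 ± 0.10. Fst, the gene of follistatin, fell by 1.48 ± 0.12 and 0.90 ± 0.12. Of 29 cell cycle genes, 12 fell and 2 rose with PTH and 15 fell with PTHrP (13 and 2, and 15 and 0, adjusted over the list alone, with adjusted p = 5.91e-09 and 1.19e-19, and adjusted p = 0.0604 and 0.0039 with an estimated correlation). Birc5, the gene of survivin, changed by -1.20 ± 0.09 with PTH and -1.14 ± 0.09 with PTHrP. Of 17 gp130 genes, 6 rose and 1 fell with PTH and 7 rose with PTHrP, also adjusted over the list alone (adjusted p = 3.37e-05 and 2.11e-05, and adjusted p = 0.00792 and 0.00596 with an estimated correlation). Osmr, a receptor gene of this family, rose by 1.17 ± 0.10 and 1.21 ± 0.10. The feedback list was no longer called, with 4 genes up and 2 down with PTH (5 and 2 adjusted over the list alone, adjusted p = 0.635) and 2 up and 2 down with PTHrP (4 and 3 adjusted over the list alone, adjusted p = 0.868). Tagln and Acta2, smooth muscle genes of the contractile cytoskeleton, fell by 1.63 ± 0.10 and 1.37 ± 0.08 with PTH and by 1.71 ± 0.10 and 1.29 ± 0.08 with PTHrP. The 3' to 5' ratio of Actb, given above, was also higher than in untreated cells with both ligands at this time, and that of Gapdh was not. In all, 1830 genes changed with PTH (894 higher, 936 lower) and 959 with PTHrP (485 higher, 474 lower). More than 2-fold, 49 were higher and 115 lower with PTH, and 41 higher and 61 lower with PTHrP. Against a 1.5-fold change 39 higher and 95 lower passed with PTH, and 31 higher and 39 lower with PTHrP. Which direction held more of all called genes was not stable. It turned for PTH with arrays shifted to 1 median (823 higher, 702 lower), the stricter filter (1015 and 979), the mean of probe sets (986 and 915), every probe set on its own (1569 and 1355), without PTHrP 1 h replicate 3 in the fit (1087 and 1067), and without PTH replicate 2 (836 and 739) or 3 (800 and 722). It turned for PTHrP after cyclic loess (559 and 601), with the array upper quartile as a covariate (595 and 757), with the replicate number as a block within each time (406 and 417), and without control replicate 2 (333 and 379) or 3 (325 and 348) or PTHrP replicate 2 (344 and 412).

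**Figure D1:**
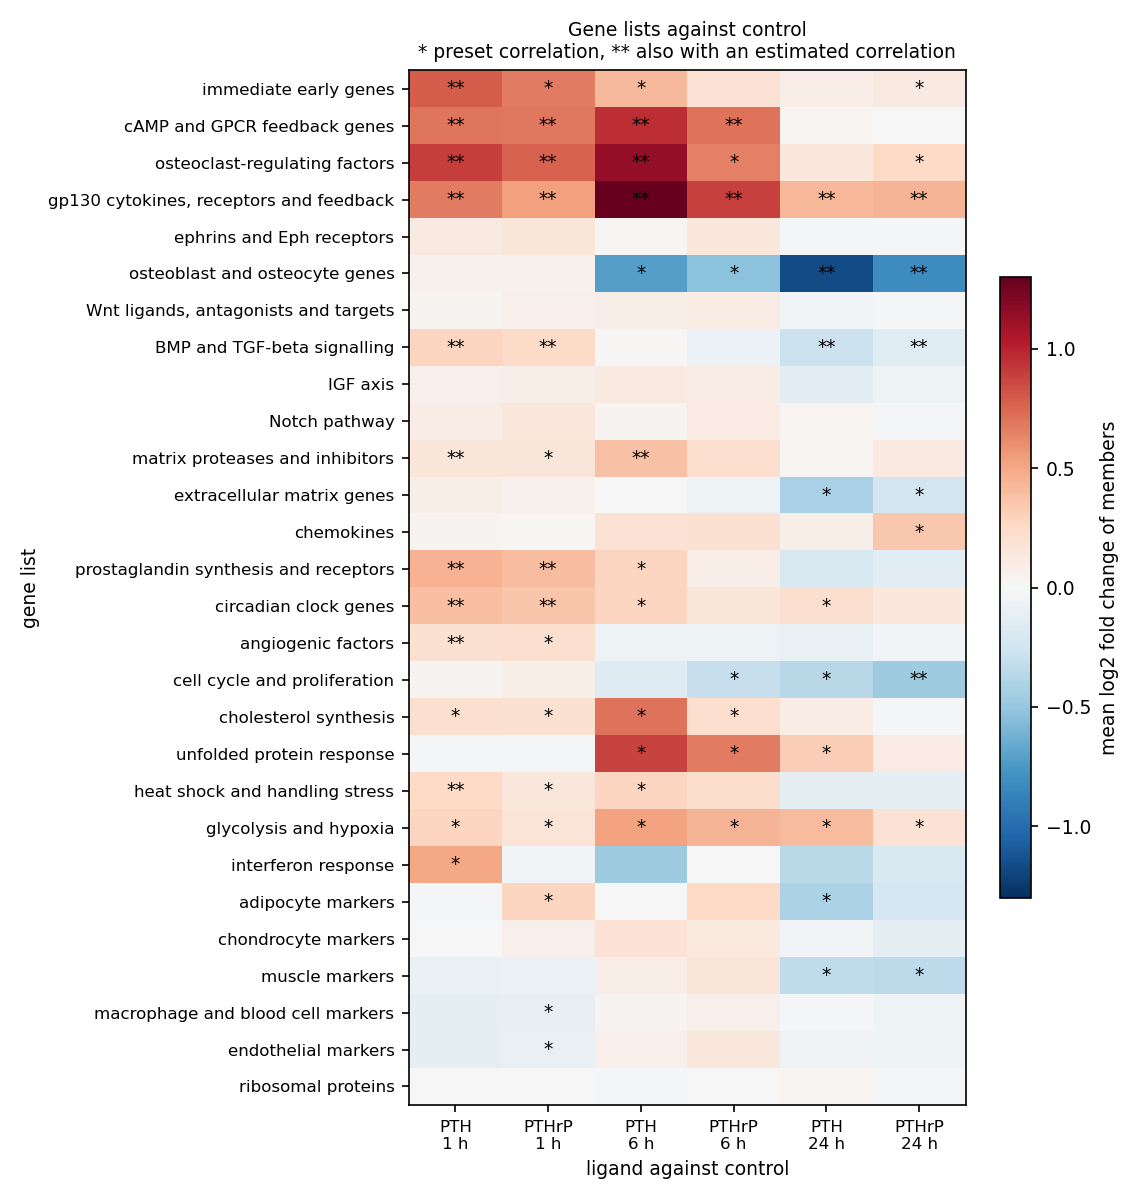
Mean log2 fold change of each of the 28 gene lists (lines) for each ligand against untreated cells at 1, 6 and 24 h (columns), with 1 star for a camera adjusted p under 0.05 at the preset correlation and 2 stars where the call also passed with an estimated correlation. At 24 h the osteoblast and osteocyte list and the BMP and TGF-beta list are lower with both ligands and carry 2 stars.

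Efnb2 was higher with both ligands at all 3 times. At 1 h it stood at 9.24 ± 0.39 with PTH and 9.01 ± 0.26 with PTHrP against 7.34 ± 0.32 in untreated cells (log2 intensity, SD, n = 3), a 3.72-fold and a 3.16-fold increase. At 6 h it rose 2.88-fold and 2.79-fold, and at 24 h 2.48-fold and 1.88-fold. In log2 units these increases were 1.89 ± 0.16 and 1.66 ± 0.16 at 1 h (SE, adjusted p = 1.56e-08 and 1.69e-07), 1.53 ± 0.16 and 1.48 ± 0.16 at 6 h (6.5e-08 and 2.2e-07), and 1.31 ± 0.16 and 0.91 ± 0.16 at 24 h (2.85e-06 and 0.000517). Of the changes in the effect with time, none passed for Efnb2: with PTH it differed by -0.37 from 1 to 6 h (adjusted p = 0.317) and by -0.22 from 6 to 24 h (0.609), and with PTHrP by -0.18 (0.651) and -0.57 (0.118). The array holds other probe sets for Efnb2, and they gave other sizes. At 1 h with PTH and PTHrP, one of them rose by 2.08 and 1.97 and another by 1.14 and 1.07, while the dimmest did not pass at 0.30 (adjusted p = 0.378) and 0.44 (0.0562). At 6 h that dimmest probe set passed at 0.72 and 0.58, and at 24 h it passed with PTH at 0.55 (0.00268) and missed with PTHrP at 0.40 (0.0523).

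Some relatives of Efnb2 also passed. Of 17 genes of ephrins and Eph receptors, 2 rose at 1 h with either ligand, Efnb2 and Epha2, a receptor of A-type ephrins, by 1.00 ± 0.13 with PTH and 1.11 ± 0.13 with PTHrP. Adjusted over the list alone, 3 rose and 1 fell with PTH and 3 rose with PTHrP. At 6 h 2 rose and 3 fell with PTH and 2 rose with PTHrP, and at 24 h 1 rose and 2 fell with PTH and 1 rose and 1 fell with PTHrP, with the same counts adjusted over the list alone. Efnb1, the gene of ephrin B1, fell with PTH at 6 h by 0.36 ± 0.09 and at 24 h by 0.56 ± 0.09, and with PTHrP at 24 h by 0.41 ± 0.09. Ephb4, the gene of a main receptor of ephrin B2, did not pass in any of the 6 comparisons, with differences from -0.08 to 0.21 and adjusted p from 0.109 to 0.797. The list was not called as a group at any time (adjusted p = 0.396, 0.168, 0.826, 0.31, 0.36 and 0.646, PTH before PTHrP at 1, 6 and 24 h). The study chose Efnb2 on these samples and the list was written around it from the title, so the counts are not independent evidence.

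**Figure D2:**
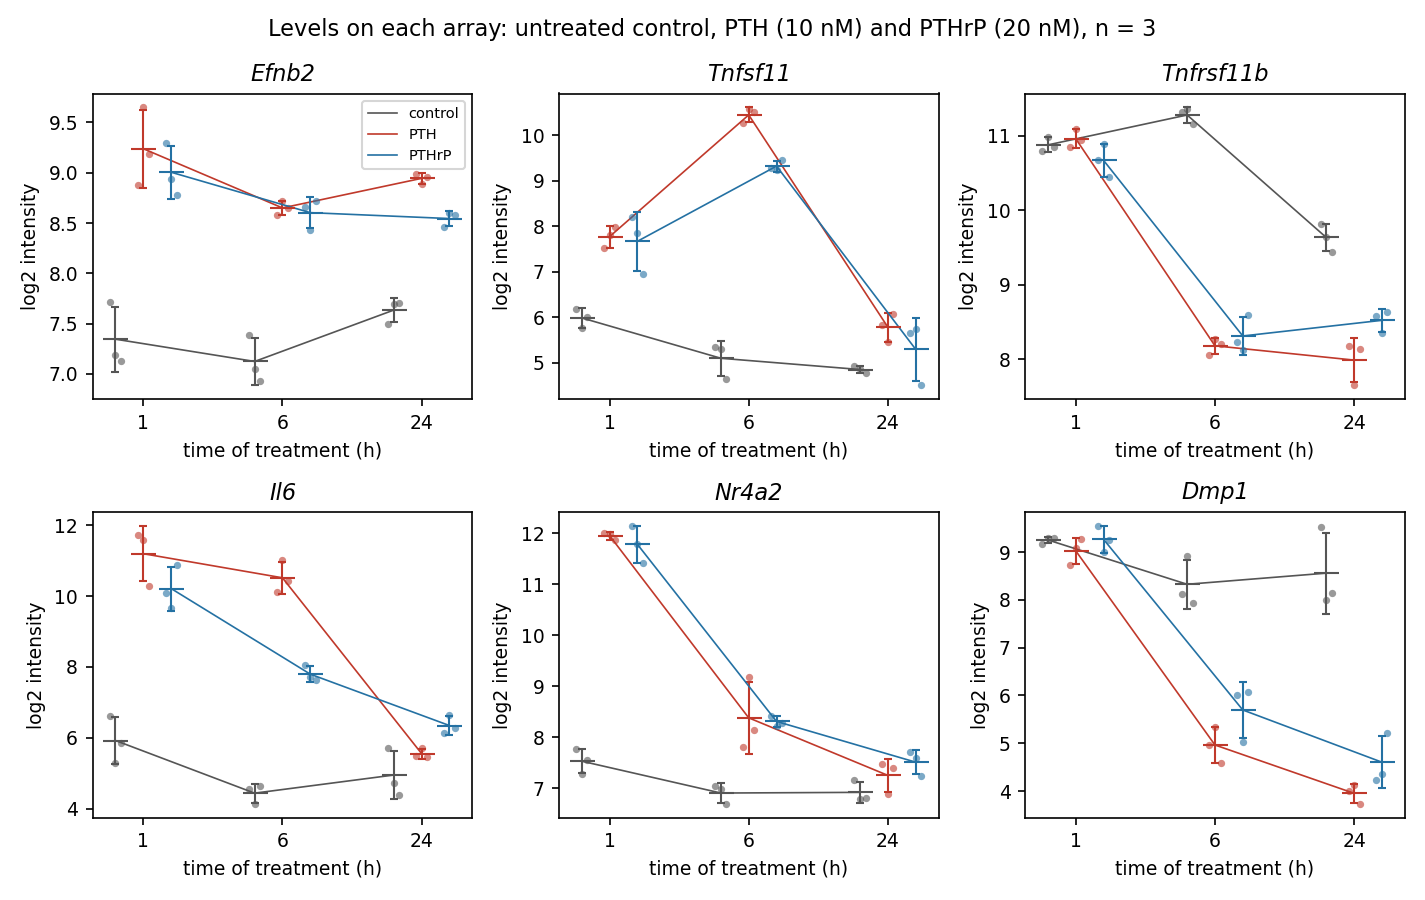
Log2 intensity of Efnb2, Tnfsf11, Tnfrsf11b, Il6, Nr4a2 and Dmp1 on each array (points) with the mean and SD of the 3 arrays of a group, for untreated cells, PTH and PTHrP at 1, 6 and 24 h. Efnb2 with PTH lies at 9.24, 8.65 and 8.94 at the 3 times, above 7.34, 7.12 and 7.63 in untreated cells.

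Set against each other, the ligands differed in more genes at 6 h than at 1 or 24 h, and at 6 h Il6, Il33 and Tnfsf11 were lower with PTHrP at 20 nM than with PTH at 10 nM. Because the doses and peptide lengths differ, ligand, peptide length and dose are not separable here. At 6 h, with PTHrP relative to PTH, Il6 was lower by -2.72 ± 0.37 log2 units (SE, n = 3), and Prg4 by -2.24 ± 0.18. Gem was lower by -2.11 ± 0.20, Il33 by -1.80 ± 0.16, and Inhba, an activin subunit gene, by -1.49 ± 0.20. Tnfsf11 was lower by -1.13 ± 0.27 (adjusted p = 0.0121). Slc40a1, the gene of the iron exporter ferroportin, was higher by 1.25 ± 0.10, Irgm1, an interferon-inducible GTPase, by 1.16 ± 0.12, and Pth1r by 0.72 ± 0.10. Of 16 cholesterol synthesis genes 12 were lower with PTHrP (13 adjusted over the list alone, adjusted p = 3.84e-14, and adjusted p = 0.0586 with an estimated correlation). Of 17 gp130 genes 8 were lower and 1 higher, also adjusted over the list alone (adjusted p = 3.01e-07, and adjusted p = 0.00316 with an estimated correlation). Of 15 osteoclast-regulating factors 5 were lower, also adjusted over the list alone (adjusted p = 6.79e-05, and adjusted p = 0.00506 with an estimated correlation). At 24 h Saa3 was higher with PTHrP by 2.44 ± 0.29, Panx3 by 1.67 ± 0.16, Ibsp by 1.29 ± 0.17, Ccl2, a chemokine gene, by 1.20 ± 0.16 and Pth1r by 0.76 ± 0.10. Prg4 and Hbegf, a growth factor gene, were lower by -1.33 ± 0.18 and -1.08 ± 0.13. Of 20 osteoblast and osteocyte genes 5 were higher with PTHrP (7 higher and 1 lower adjusted over the list alone, adjusted p = 1.98e-12, and adjusted p = 0.00862 with an estimated correlation).

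At 1 h no single gene passed for PTHrP against PTH, but camera called several lists from small shifts of their members. By limma, 0 genes differed, and the lowest adjusted p was 0.725. Of 15711 genes, 632 had an unadjusted p under 0.05, a smaller share than the 0.05 that no difference would give. The 17 gp130 genes were lower with PTHrP by a mean of -0.14 log2 units, with 0 adjusted over the list alone (adjusted p = 8.57e-05, and adjusted p = 0.0353 with an estimated correlation). Interferon response genes were lower by a mean of -0.54 and adipocyte markers higher by 0.30, with 0 of 16 and 2 of 12 adjusted over the list alone (adjusted p = 3.36e-16 and 6.38e-06, but adjusted p = 0.153 and 0.265 with an estimated correlation). Immediate early genes were lower by a mean of -0.11, with 0 of 29 adjusted over the list alone (adjusted p = 1.14e-06, and adjusted p = 0.265 with an estimated correlation), a call lost without PTHrP replicate 1 (adjusted p = 0.107). Glycolysis and hypoxia genes, heat shock genes and osteoclast-regulating factors were also called as lower, with 0 members of each adjusted over the list alone (adjusted p = 7.84e-05, 0.00413 and 0.0327, and adjusted p = 0.556, 0.308 and 0.153 with an estimated correlation). The glycolysis call was lost without PTH replicate 3 (adjusted p = 0.207) and the heat shock call without PTHrP replicate 3 (adjusted p = 0.199). The osteoclast call was lost without PTH replicate 1 or 2 or PTHrP replicate 2 or 3 (adjusted p from 0.06 to 0.347).

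Several genes did not pass between the ligands after adjustment over all genes. The 95% intervals of their differences, which are not adjusted, bound what could have been missed. Where an adjusted p is printed, the interval does not cover equal levels. At 24 h Efnb2 lay at 8.88 to 8.99 on the PTH arrays and 8.46 to 8.60 on the PTHrP arrays (log2 intensity), without overlap. Tnfrsf11b lay at 7.65 to 8.18 and 8.35 to 8.63 at 24 h, also without overlap. For Efnb2 the difference of PTHrP from PTH was -0.23 (-0.57 to 0.10) at 1 h, -0.05 (-0.39 to 0.29) at 6 h and -0.40 (-0.74 to -0.06, adjusted p = 0.366) at 24 h. For Tnfsf11 it was -0.10 (-0.67 to 0.46) at 1 h and -0.49 (-1.05 to 0.08) at 24 h. For Il6 it was -0.98 (-1.74 to -0.23, adjusted p = 0.926) at 1 h, and for Tnfrsf11b it was 0.13 (-0.16 to 0.42) at 6 h and 0.53 (0.25 to 0.82, adjusted p = 0.0621) at 24 h. At 6 h 1197 differed (699 higher with PTHrP, 498 lower), and with all arrays shifted to 1 median 726 did, of which 44.9% were higher instead of 58.4%. Fewer were higher than lower also without PTH replicate 1 (498 and 537) or PTHrP replicate 1 (328 and 425). The same held with only the arrays compared (366 and 403), every probe set on its own (874 and 930) and against a 1.5-fold change (1 and 6). More were higher after cyclic loess (1075 and 659), with array weights (2751 and 1789) and with the array upper quartile as a covariate (1323 and 816). At 24 h 182 differed (132 higher, 50 lower). The 6 h count was 629 and 711 without PTH replicates 2 and 3 and 753 and 669 without PTHrP replicates 1 and 3, and the 24 h count was 101 and 96 without PTH replicates 2 and 3 and 77 without PTHrP replicate 3.

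The responses to PTH at 10 nM and PTHrP at 20 nM ran in parallel, with different sizes. At 6 h, over the 385 genes that changed more than 2-fold by the mean of both ligands, the mean shift from control was 1.77 ± 0.04 log2 units with PTH and 1.35 ± 0.04 with PTHrP (SD, n = 3), a ratio of 0.765 with no overlap of arrays (exact p = 0.1, the smallest possible). Of these genes, 180 passed as smaller with PTHrP and 3 as larger. At 1 h the ratio was 0.93 over 71 genes (exact p = 0.5) and at 24 h it was 0.825 over 121 genes (exact p = 0.1), with 1.05 for those that rose (exact p = 0.4) and 0.736 for those that fell (exact p = 0.1). Genes called with both ligands in the same direction numbered 220 at 1 h (192 higher, 28 lower), 2647 at 6 h (1088 higher, 1559 lower) and 773 at 24 h (378 higher, 395 lower), and 0, 1 and 1 were called in opposite directions. Independent calls would share 3.5 higher and 0.1 lower genes at 1 h, 155.7 and 344.3 at 6 h, and 27.6 and 28.2 at 24 h. The correlation of the changes across genes, which are not independent replicates, was 0.813, 0.895 and 0.840, where the shared control arrays alone gave 0.501, 0.502 and 0.5 in simulated data. The covariance was 0.0298, 0.125 and 0.0458 at 1, 6 and 24 h, against 0.00679, 0.00682 and 0.00677 from the shared control arrays alone in the simulated data. That noise was drawn separately for each gene. A deviation of the control arrays that many genes share could give larger values than the simulated ones. The number of shared calls was not computed with divided controls. Of 53, 1957 and 1056 genes called with PTH alone at 1, 6 and 24 h, the ligands themselves differed in 0, 480 and 89, and of 65, 640 and 185 called with PTHrP alone they differed in 0, 114 and 16. Without replicate 3 of the PTHrP 1 h group, 379 genes were shared at 1 h.

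**Figure D3:**
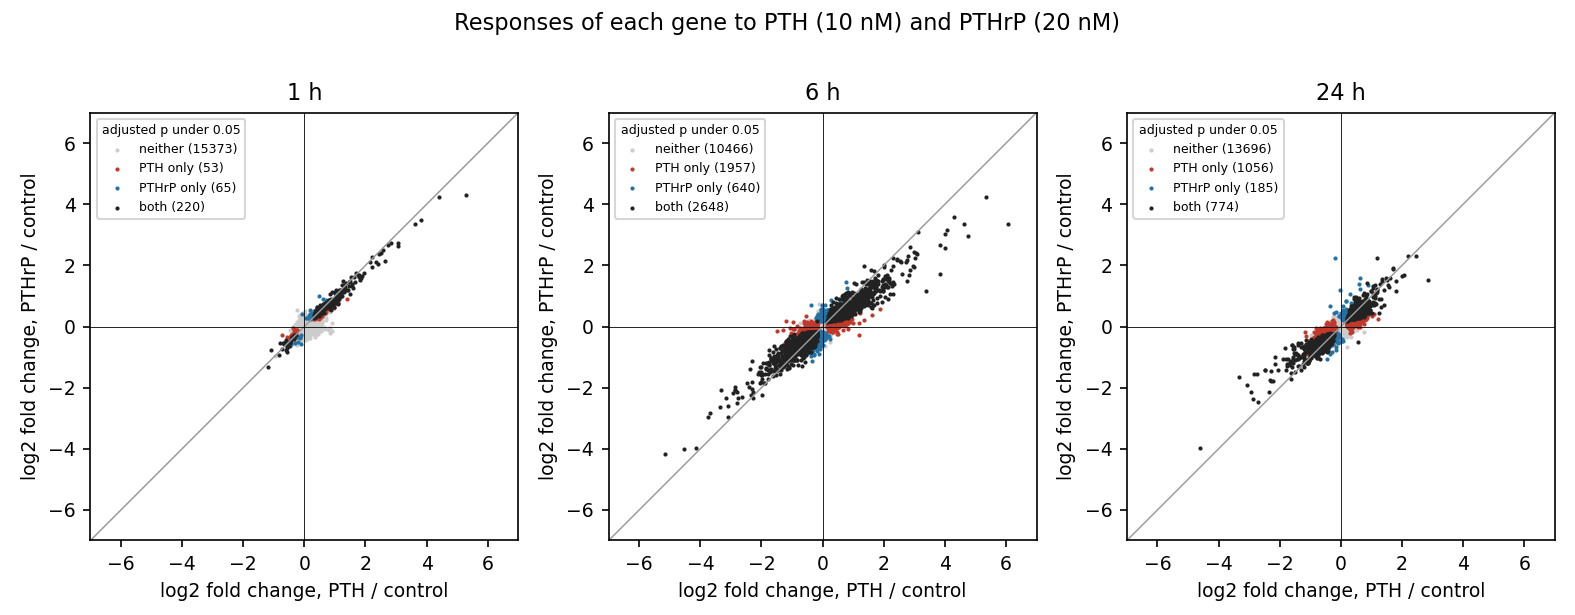
Log2 fold change with PTHrP at 20 nM against that with PTH at 10 nM for each gene tested, at 1, 6 and 24 h, coloured by whether the gene was called with PTH alone, PTHrP alone or both. Genes called with both in the same direction number 220, 2647 and 773 at the 3 times. The diagonal marks equal responses. At 6 h, 90.6% of the 385 genes that changed more than 2-fold by the mean of both ligands had a smaller change with PTHrP.

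The effect of each ligand changed with time for many genes. The effect of PTH on Tnfsf11 grew by 3.56 ± 0.39 log2 units (SE) from 1 to 6 h and then dropped by 4.42 ± 0.39 to 24 h, and that of PTHrP changed by 2.54 ± 0.39 and -3.78 ± 0.39. For Tnfrsf11b the effect of PTH moved by -3.18 from 1 to 6 h and by 1.45 from 6 to 24 h. For Nr4a2 it moved by -2.95 and then by -1.14 (adjusted p = 0.0152). Il6 did not pass for a change from 1 to 6 h with PTH, at 0.81 (adjusted p = 0.327), and its effect dropped by 5.48 from 6 to 24 h. Between 1 and 6 h the effect differed for 2914 genes with PTH and 1915 with PTHrP, and between 6 and 24 h for 3211 and 1903. Of the genes called with PTH at both 1 and 6 h, 164 were higher at both times, 27 lower at both and 15 opposite, where independent calls would share 25.7 higher and 8.4 lower. Between 6 and 24 h these numbers were 308, 462 and 249, against 101.8 and 167.8. With PTHrP they were 142, 20 and 21 (21.4 and 4.8) and then 204, 228 and 80 (42.2 and 58). Calls of different times rest on different control arrays, while PTH and PTHrP share the control arrays of each time. Without replicate 3 of the PTHrP 1 h group the change of the PTHrP effect from 1 to 6 h was called for 4087 genes.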

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

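The test for a mislabelled sample, the tests with the array upper quartile as a covariate, the ratio of the responses, and the lists with 1 array left out were chosen only after the results had been seen.

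The effect of a ligand differed between times by the test of the difference itself for 2914 genes with PTH between 1 and 6 h and for 3211 between 6 and 24 h, and with PTHrP for 1915 and 1903. From 1 to 6 h the effect of PTH moved up most for the cytokine gene Il33 by 4.555, Cited1, a transcriptional co-regulator, by 4.01, and Ramp3 by 3.66 log2 units, and moved down most for Smpd3 by -5.08, Dock10 by -4.84 and Car8 by -4.19. From 6 to 24 h it moved up for Ndnf by 2.53, Dtx4 by 2.525 and Slc40a1 by 2.34 and moved down for Il6 by -5.48, Vdr by -4.54 and Tnfsf11 by -4.42. A move up can be a growing increase or a fading decrease. With PTHrP, from 1 to 6 h the differences were 3.00 for Cited1, 2.88 for Il33, 2.54 for Tnfsf11, -4.10 for Smpd3, -4.07 for Dock10 and -3.99 for Car8. From 6 to 24 h they were 2.47 for Cd200, 2.44 for Dock10, 2.40 for Btla, -3.78 for Tnfsf11, -3.53 for Vdr and -3.32 for Il11. Each of these 24 differences is the largest or among the 3 largest of its direction for its ligand and interval. Of 100 drawn splits of the 12 arrays of each test, 1, 3, 4 and 4 gave as many genes, the real one included, for PTH from 1 to 6 h and 6 to 24 h and PTHrP in the same order. The highest counts of the other splits were 2700, 3874, 2787 and 2988. Such splits mix arrays of different times and treatments, which themselves differ, so they do not stand for an absence of change and do not settle whether chance can be excluded.

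Probe sets without a single gene symbol, 6650 past the filter, were outside the comparisons of genes. Of these, 198 changed with PTH at 1 h (162 higher, 36 lower), 118 with PTHrP at 1 h (76 and 42), 651 with PTH at 6 h (271 and 380), 406 with PTHrP at 6 h (149 and 257), 178 with PTH at 24 h (99 and 79) and 91 with PTHrP at 24 h (56 and 35).

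At 6 h the responses to PTHrP at 20 nM were 0.765 of those to PTH at 10 nM. A compressed intensity scale on the PTHrP arrays would lower the spread of all genes alike, but the SD across genes with PTHrP was 0.982 of that with PTH. With each of the 9 arrays left out in turn the ratio was at most 0.781, and with the array upper quartile as a covariate it was 0.759, so neither a single array nor that axis of the intensities accounts for it. A smaller response of these cells to PTHrP at the doses used is therefore a hypothesis that these tests leave standing. The ligand, the peptide length and the labelled dose, which differ together, stay open as its source.

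Interferon response genes were higher with PTHrP than with PTH at 6 h, 4 of 16 (6 adjusted over the list alone, adjusted p = 0.00196, but adjusted p = 0.641 with an estimated correlation, and 0.149 without PTH replicate 2), a mean difference of 0.461 (exact p = 0.2). At 1 h the same list went the other way, by -0.536 (exact p = 0.2, adjusted p = 3.36e-16, but adjusted p = 0.153 with an estimated correlation), with 0 of 16 genes past the threshold by limma. Of all 15711 genes, 632 had an unadjusted p under 0.05 there, a smaller share than the 0.05 that no difference would give. At 6 h the difference was 0.475 with the array upper quartile as a covariate, which argues against that axis of the intensities. The list mean ranged over 0.945 among the 3 arrays of the PTH 6 h group, more than the difference at either time, and the groups overlapped at both, so differences between cultures unrelated to the ligand are a candidate explanation. A difference due to the ligand, its length or its dose stays open.

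Array 3 of PTHrP at 1 h stood apart from its group, with a lowest correlation of 0.9831 against 0.992 in any other group. Over the 71 genes that changed more than 2-fold at 1 h by the mean of both ligands, its shift from control was 0.849 of that of the other PTHrP arrays. A shift of that size argues against a mislabelled untreated sample, though array 3 was among the arrays used to pick these genes. After cyclic loess between arrays its lowest correlation was 0.9841, still below 0.9925, the lowest of the other groups. A smooth change of the intensity scale alters such a correlation little. The test therefore cannot decide whether an intensity distribution left by the normalization sets array 3 apart. Against the other arrays of its group its unfolded protein response genes were higher by 0.52 log2 units and its cholesterol synthesis genes differed by -0.36, and endothelial, muscle, and macrophage and blood cell markers were higher by 0.37, 0.36 and 0.28, as were 3024 genes with a mean log2 under 6 by 0.24, while 4702 genes with a mean log2 of at least 9 differed by -0.12. No biological explanation was tested, and a difference in its RNA or labelling stays open.

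The splits of the 6 arrays of each comparison of 2 groups number 10, too few for a share under 0.05. Every split but the real one puts arrays of both groups on each side. A real difference then widens the spread and lowers the count, so low counts of other splits are no measure of chance. Only the real split gave as many genes (1 of 10) for PTH at 1 h (273, highest other 1), 6 h (4605, other 0) and 24 h (1830, other 0), for PTHrP at 6 h (3288, other 0) and 24 h (959, other 0), for PTHrP against PTH at 6 h (1197, other 0) and 24 h (182, other 1), and for untreated cells at 6 h (356, other 0) and 24 h (3635, other 0). For PTHrP at 1 h, 2 of 10 splits gave as many: against 285 genes, 695 passed when control replicate 2 and PTHrP replicates 1 and 2 were set against the other 3 arrays. That split is the real one with control replicate 2 and PTHrP replicate 3, the array that stood apart, exchanged. The cause of its larger count was not tested. For PTHrP against PTH at 1 h, where 0 genes passed, all 10 gave as many, with 53 as the highest. For the number of lists called, the real values were 13, 15, 12, 8, 10 and 10 for PTH and PTHrP at 1, 6 and 24 h, the highest others 11, 11, 12, 10, 11 and 9, and the splits with as many 1, 1, 2, 4, 3 and 1, the real one included. For both ligands at 6 h and PTH at 24 h, mixed splits thus called as many lists or more. The number of lists called at the preset correlation does not tell the real grouping from mixed ones there. Of 100 drawn splits of the 9 arrays of each time, 4, 3 and 1 gave as large an overlap of the ligands as 220, 2647 and 773 genes at 1, 6 and 24 h, with 325, 2897 and 118 as the highest of the others. These splits mix treated and untreated arrays, so they too leave open whether chance can be excluded.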

How the results depend on the processing

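The tests with the array upper quartile as a covariate, without array 3 of PTHrP at 1 h, with a block for the arrays of untreated cells and PTHrP at 1 h, of the ratio of the responses, and of the lists and the overlap under further settings were chosen only after the results had been seen. The counts were within 1.5 times the reported ones with no filter, a stricter filter, the mean of a gene's probe sets, a trended and robust prior, and the replicate number as a block over all arrays. Unless a cause is given, the cause of a change was not tested. No scaling moved the median of all genes by more than 0.1 log2 units. Of 615 values for named genes, 606 kept their direction and side of the threshold after cyclic loess, 602 with arrays shifted to 1 median and 359 against a 1.5-fold change, which asks for more by construction. Of 3834 values with 1 array left out, 3583 did so, 235 were lost and 16 gained, with fewer arrays. The median SE of 0.102 and dim probe sets, whose fold changes are understated, limit what could be seen. Once group means were removed, arrays of the same replicate number at the same time had a median correlation of 0.007, against 0.013 for different numbers. In untreated cells and PTHrP at 1 h, 1 of 9 pairs of groups, every same-numbered pair correlated over 0.1 (0.188 to 0.449, others -0.38 to 0.2), and 5 of 6 arrays correlated best with their own number. With the number as a block for those arrays, 308 genes passed for PTHrP at 1 h instead of 285. Of 28 lists and 75 named genes there, that block changed the call of 1, Has2, which then passed.

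Counts are given for PTH and PTHrP at 1, 6 and 24 h in turn. With every probe set on its own, which tests more features, 526, 510, 7906, 5577, 2924 and 1470 passed. PTHrP against PTH gave 1 at 1 h and 1804 at 6 h. The changes with time gave 4757 and 5375 with PTH and 3012 and 3047 with PTHrP, untreated cells gave 638 at 6 h and 6138 at 24 h, and the ligands shared 388, 4411 and 1200. Array weights, which give less weight to arrays that stand apart, gave 802 with PTH and 1764 with PTHrP at 1 h, 6952 with PTHrP at 6 h, and 4388 and 2079 at 24 h. They gave 4540 and 1273 for PTHrP against PTH at 6 and 24 h, 5128 for PTH from 6 to 24 h, 6229 and 4979 for PTHrP from 1 to 6 h and 6 to 24 h, 1307 and 5651 in untreated cells, and 589, 4293 and 1585 shared. Against a 1.5-fold change, 58, 51, 569, 286, 134 and 70 passed, 7 and 2 for PTHrP against PTH at 6 and 24 h, 335 and 294 for the changes with time of PTH, 165 and 106 for PTHrP, 16 and 319 in untreated cells, and 51, 269 and 63 shared. Efnb2 with PTHrP at 24 h, at 0.91, did not pass against that size (adjusted p = 1). With arrays shifted to 1 median, 726 differed for PTHrP against PTH at 6 h, and after cyclic loess 283 did at 24 h. After cyclic loess the share of higher calls was 51.1% instead of 30.7% for PTHrP from 1 to 6 h and 46.5% instead of 58.4% for PTHrP from 6 to 24 h. For untreated cells at 24 h, reported as 1821 higher and 1814 lower, lower calls were more numerous with arrays shifted to 1 median (1440 and 1664) and after cyclic loess (1879 and 2254).

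With only the arrays of the groups compared, 103 passed for PTHrP at 1 h, 769 and 83 for PTHrP against PTH at 6 and 24 h, 2913 for PTHrP from 6 to 24 h, 584 for untreated cells at 6 h, and 101 were shared at 1 h. With the replicate number as a block within each time, 117 differed between the ligands at 24 h, and 80 and 2279 in untreated cells at 6 and 24 h. The upper quartile as a covariate gave 2139 and 378 for PTHrP against PTH at 6 and 24 h and 715 for untreated cells at 6 h. Without array 3 of PTHrP at 1 h in the fit of all arrays, 442 passed for PTH at 1 h and 585 for untreated cells at 6 h. At an adjusted p of 0.01, 493 were shared at 24 h. The dimmest probe set of Efnb2 gave 0.30 and 0.44 at 1 h and 0.40 with PTHrP at 24 h, none of which passed. With an estimated correlation 6 lists were called for PTHrP at 1 h, 4 and 2 at 6 h, and 3 and 4 at 24 h, and fry, which does not set a list against other genes, called 18 for PTHrP at 6 h.

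With 1 array left out, counts ran from 193 to 931 for PTHrP at 1 h, the highest without PTHrP replicate 3. For PTHrP against PTH they ran from 0 to 1 at 1 h (1 without PTHrP replicate 2), 629 to 1035 at 6 h and 77 to 193 at 24 h. For PTHrP from 1 to 6 h they ran from 1434 to 4087, the highest without PTHrP 1 h replicate 3, and for untreated cells at 6 h from 175 to 301. Shared genes at 1 h ran from 168 to 379. A few directions reversed. Hspa8 with PTHrP at 6 h was -0.046 with the mean of its probe sets (adjusted p = 0.689) against 0.17 reported. By fry the angiogenic factors moved the other way at 6 h (adjusted p = 0.0056 with PTH and 0.0163 with PTHrP), where camera called neither. For the list unfolded protein response, PTH against control, 1 h, not called with all arrays, the adjusted p ran from 0.00184 (without control replicate 1) to 0.667, and without PTH replicate 2 it was 0.00362 with the direction reversed. For the list unfolded protein response, PTHrP against control, 1 h, also not called with all arrays, it ran from 0.0104 (without PTHrP replicate 2) to 0.23, and it was 0.0104 there and 0.0337 without control replicate 1 with the direction reversed. This list also passed in the direction of all arrays for PTHrP without control replicate 2 (0.0268) or PTHrP replicate 3 (0.0305).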

Other observations

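The further settings for the gene lists were tests chosen only after the results had been seen.

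Camera also called other lists at 1 h, from a few of their members. Of 18 clock genes, 3 rose with either ligand (3 with PTH and 4 with PTHrP adjusted over the list alone, camera adjusted p = 5.91e-07 and 5.37e-05, and adjusted p = 0.00251 and 0.0117 with an estimated correlation), among them Nfil3, a repressor in the clock, by 2.45 ± 0.15 and 2.37 ± 0.15 log2 units (SE, n = 3) and Per1 by 1.62 ± 0.10 and 1.63 ± 0.10. Of 18 angiogenic factors, 2 rose with either ligand, also adjusted over the list alone (adjusted p = 0.00263 and 0.00401, and adjusted p = 0.0453 and 0.0512 with an estimated correlation), among them Vegfa, the main vessel growth factor gene, by 1.57 ± 0.11 and 1.38 ± 0.11. Of 22 matrix proteases and inhibitors, 2 rose with either ligand, also adjusted over the list alone (adjusted p = 0.0131 and 0.0182, and adjusted p = 0.0453 and 0.0551 with an estimated correlation). Those protease calls were lost with PTH without control replicate 3 (0.0633) or PTH replicate 1 (0.0949) and with PTHrP without control replicate 3 or PTHrP replicate 3, where the adjusted p was 0.1 to 0.159. At 6 h 7 protease genes rose and 2 fell with PTH (8 and 3 adjusted over the list alone, adjusted p = 0.00304, and adjusted p = 0.0299 with an estimated correlation) and 5 rose and 2 fell with PTHrP (8 and 2 adjusted over the list alone, adjusted p = 0.0779). Plaur, the urokinase receptor gene, rose by 2.61 ± 0.15 and 1.73 ± 0.15 at 6 h, and Timp1, an inhibitor of matrix proteases, by 1.59 ± 0.09 and 1.11 ± 0.09. The Notch target Hes1 rose by 1.41 ± 0.12 and 1.21 ± 0.12 at 1 h, and Sox9, a transcription factor of chondrocytes, by 1.06 ± 0.09 and 0.92 ± 0.09. Of 30 Wnt genes, 9 rose and 10 fell with PTH at 6 h and 8 rose and 5 fell with PTHrP, also adjusted over the list alone (adjusted p = 0.643 and 0.513). The ligand gene Wnt4 rose by 2.02 ± 0.13 and 1.94 ± 0.13 and Sfrp1, a secreted Wnt antagonist, by 1.78 ± 0.11 and 1.45 ± 0.11, while Ccn4, a Wnt target, fell by 1.47 ± 0.08 and 1.07 ± 0.08. At 24 h the Wnt antagonist gene Wif1 rose by 1.59 and 1.31.

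Of 18 chemokine genes, 5 rose with PTHrP at 24 h (5 up and 1 down adjusted over the list alone, adjusted p = 0.000634, and adjusted p = 0.238 with an estimated correlation), among them Ccl2 by 1.19 ± 0.16 and Ccl7 by 1.05 ± 0.14. Of 14 genes of the IGF axis, 4 rose and 2 fell with PTH at 6 h (5 and 2 adjusted over the list alone, adjusted p = 0.566), with the binding protein gene Igfbp3 up by 1.09 ± 0.13. Markers of other cell types were also measured. Of 12 adipocyte markers, 4 fell with PTH at 24 h (6 adjusted over the list alone, adjusted p = 0.00297, and adjusted p = 0.437 with an estimated correlation), among them Retn by 1.01 ± 0.16. At 1 h 0 adipocyte markers passed with PTHrP, also adjusted over the list alone, although the list was called as higher by camera (adjusted p = 0.000825, and adjusted p = 0.355 with an estimated correlation). Of 11 muscle markers, 2 fell at 24 h with either ligand, Tagln and Acta2, also adjusted over the list alone (adjusted p = 0.00351 and 0.000463, and adjusted p = 0.335 and 0.238 with an estimated correlation). Stromal cells express both of these genes. Of 13 chondrocyte markers, 1 rose and 3 fell at 24 h with either ligand, also adjusted over the list alone (adjusted p = 0.206 and 0.0674), with Col10a1, a collagen gene of hypertrophic cartilage, at -1.12 ± 0.14 and -1.10 ± 0.14. Of 10 markers of macrophages and blood cells and 12 endothelial markers, 0 passed at 1 h with PTHrP, also adjusted over the list alone, while camera called both lists as lower (adjusted p = 0.0455 and 0.0349), with adjusted p = 0.443 and 0.461 with an estimated correlation. Without control replicate 3, PTHrP replicate 1 or PTHrP replicate 2 these calls were lost (adjusted p from 0.0668 to 0.47 and from 0.164 to 0.407), and after cyclic loess they were lost as well. At 6 and 24 h neither list was called. Of 14 ribosomal protein genes, whose levels seldom change, 1 rose with PTH at 6 h, also adjusted over the list alone, and the list was not called with either ligand at any time (adjusted p from 0.635 to 0.951).

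Heat shock, interferon and Notch genes gave the following values. Of 11 heat shock genes, 1 rose at 1 h with PTH (3 adjusted over the list alone, adjusted p = 7.94e-06, and adjusted p = 0.0453 with an estimated correlation). With PTHrP 1 rose at 1 h (2 adjusted over the list alone, adjusted p = 0.0434, but adjusted p = 0.424 with an estimated correlation), a call lost without control replicate 1 or 3 or PTHrP replicate 1 or 2 (adjusted p from 0.056 to 0.196) and after cyclic loess. At 6 h 5 rose with PTH (6 up and 1 down adjusted over the list alone, adjusted p = 0.0329, but adjusted p = 0.415 with an estimated correlation), a call lost without control replicate 1 or 3 or PTH replicate 2 (adjusted p from 0.0578 to 0.0897). With PTHrP 4 rose at 6 h (4 up and 1 down adjusted over the list alone, adjusted p = 0.109). Hmox1, a heme-degrading enzyme gene induced by stress, rose by 1.32 ± 0.15 and 0.75 ± 0.15 at 6 h. Of 16 interferon response genes, 0 passed with PTH at 1 h, also adjusted over the list alone, but their mean difference was 0.50 and camera called the list (adjusted p = 6.94e-08, and adjusted p = 0.186 with an estimated correlation). In untreated cells 10 of them were higher at 24 h than at 1 h (13 adjusted over the list alone, adjusted p = 2.37e-07, and adjusted p = 0.259 with an estimated correlation). Of 15 Notch genes, 2 rose with PTH at 1 h and 3 with PTHrP (3 up and 1 down and 4 up and 1 down adjusted over the list alone, adjusted p = 0.222 and 0.0856). Of 168 tests of a list in a comparison with untreated cells, 26 had a median, a mean and a test that differed in sign, of which 0 were called (lowest adjusted p = 0.168).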
